A study of Citrus maxima with 12 samples.

How the data were processed

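RNA was sequenced from fruit of pomelo (Citrus maxima) in 12 libraries. Per the labels' protocols, RNA was purified with an RNeasy Mini Plus kit and libraries were made with a SMARTer mRNA-seq kit. The authors deposited a single table of FPKM values (fragments per kilobase of gene, scaled to the fragments of the library), holding 32863 gene IDs. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The table carries no gene names, descriptions or coordinates, and no reference was used, so genes appear under the IDs of the file only. For the same reason the 35 gene lists (pathways, defence families, transcription factor families and markers of other tissues) that had been fixed as search terms on gene descriptions could not be filled or tested. The table also holds 6 columns that match none of the 12 labelled samples. They were not analysed here.

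Samples were grouped by the cultivar and treatment in their labels into Taoxi control, Taoxi disease, Jinlan disease and Jinsha disease, with 3 libraries each, and columns were matched to samples by title. The labels call the libraries of a group biosamples and do not say whether they came from separate fruits or trees, so p-values measure the spread between these samples, which may be technical in part. No 2 libraries held identical values. FPKM values keep no read totals. The low values were examined for whole-read steps: among IDs below 0.3 FPKM in both libraries of a replicate pair, at most 1.81% fell in the most common 0.02-wide bin of the log2 ratio, over 4 pairs tested, so whole reads were not recovered and the depth behind each value is unknown. No counting interval is given for that reason.

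From the deposited FPKM, genes at 1 FPKM or more in at least 3 of the 12 libraries were kept (17421 of 32863 IDs; 7390 IDs were at 0 in all 12). Values were taken as log2(FPKM + 1) with no further scaling between libraries. A linear model with one mean per group was fitted over all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), so that all comparisons share one estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, and a gene passed at an adjusted p below 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The pseudocount, the filter and the test were set before the data were examined, as were the 4 comparisons between groups, the test of the Taoxi genes in Jinlan against Jinsha, the alternatives and the rule for naming genes. By that rule, with no names to go by, each comparison names the 2 IDs with the largest rise and the 2 with the largest fall among those that passed and whose groups did not overlap. Sets of genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The Taoxi genes followed in Jinlan against Jinsha were also compared with 10000 random sets of other genes, drawn within 20 bins of the fitted spread by 5 bins of mean expression. This comparison, and the overlap between Jinlan and Jinsha against Taoxi, were added after the data had been seen. Repeated rows were looked for, and 18 IDs with values above 0 had the values of another ID in every library. None of them entered the tests.

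The model was tested on simulated data made from the real gene means and residual spreads, over 17421 genes of which 100 were changed by 1 log2 unit and 100 by 2. In the simulated Taoxi comparison 73 of the former and 98 of the latter were recovered, with 10 false calls among 181. In the simulated comparison of Jinlan with Jinsha 73 and 90 were recovered, with 8 false calls among 171. For each gene, all simulated libraries had the same spread. The real Taoxi controls spread more widely than the other groups, so these rates may not carry over to the real comparisons. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-ratio, upper-quartile and quantile scaling, rescaling to TPM, a fit of only the groups compared, the replicate number as a block, a robust variance prior, a fold threshold of 2, and leaving out each library in turn. Weights per library (limma arrayWeights), and leaving out Taoxi control 1 from the comparisons it does not belong to, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.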

Results

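Fruit transcriptomes of 3 pomelo cultivars were compared in a study of Jinggang honey pomelo and its black spot disease. Taoxi was represented by control and by diseased fruit, and Jinlan and Jinsha by diseased fruit. Control fruit of Jinlan and Jinsha was not analysed here. Each of the 4 groups had 3 libraries. The FPKM of a library summed to between 560349 and 577783, and between 21345 and 22431 gene IDs were above 0. The deposited table does not pair its IDs with gene names, so genes are given by ID and their functions are not stated.

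The libraries separated by cultivar more than by disease state within Taoxi, the only cultivar compared here in both states. The first principal component of log2(FPKM + 1) held 73% of the variance and set 5 of the 6 Taoxi libraries (scores of 60.1 to 85.3) apart from the 6 Jinlan and Jinsha libraries (-57.6 to -51.4). The second component held 11.1% and separated Jinsha (32.6 to 35.0) from Jinlan (-30.9 to -30.5). Within Taoxi, controls 2 and 3 scored 82.7 and 85.3 on the first component and diseased fruit 60.1 to 64.1. The third component held 7.52% and set Taoxi controls 2 and 3 (28.6 and 35.9) apart from diseased Taoxi (-31.0 to -19.5). Replicates of diseased Jinlan correlated at 0.991 to 0.994 (Pearson's r across genes), those of diseased Jinsha at 0.991 to 0.993 and those of diseased Taoxi at 0.987 to 0.990. The Taoxi controls correlated at 0.887 to 0.992.

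**Figure D1:**
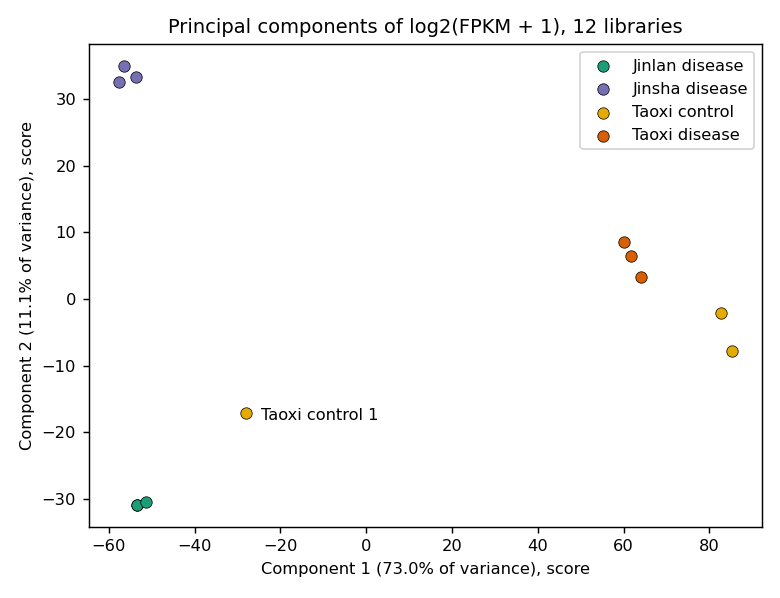
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1) over 17421 genes, in arbitrary score units, 1 point per library and colours for the groups. Taoxi control 1 lies at -28.0 on the first component, between diseased Jinlan and the other 5 Taoxi libraries, which lie at 60.1 or above.

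The wide range in the Taoxi controls came from the library labelled Taoxi control 1. Its mean correlation was 0.891 with the other Taoxi controls, 0.912 with diseased Taoxi, 0.960 with diseased Jinsha and 0.975 with diseased Jinlan. Taoxi controls 2 and 3 correlated with diseased Jinlan at 0.844 and 0.839. Genes near 0 in one set of cultivars showed the position of this library, and were picked without using it. For 26 IDs that were at 0.1 FPKM or less in all 6 Jinlan and Jinsha libraries and at 3 FPKM or more in the other 5 Taoxi libraries, Taoxi control 1 stood at a median of 0.125 times the mean of Taoxi controls 2 and 3 (quartiles 0.103 and 0.153). All 26 were below 0.5 times that mean, while the ratio of Taoxi control 2 to Taoxi control 3 over the same IDs had a median of 0.990. For 23 IDs at 0.1 FPKM or less in the other 5 Taoxi libraries and at 3 FPKM or more in all Jinlan and Jinsha libraries, Taoxi control 1 stood at a median of 0.812 times the diseased Jinlan mean (quartiles 0.681 and 0.931). This library stayed in its labelled group in the values below, and the numbers of passing genes in each comparison are also given without it.

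**Figure D2:**
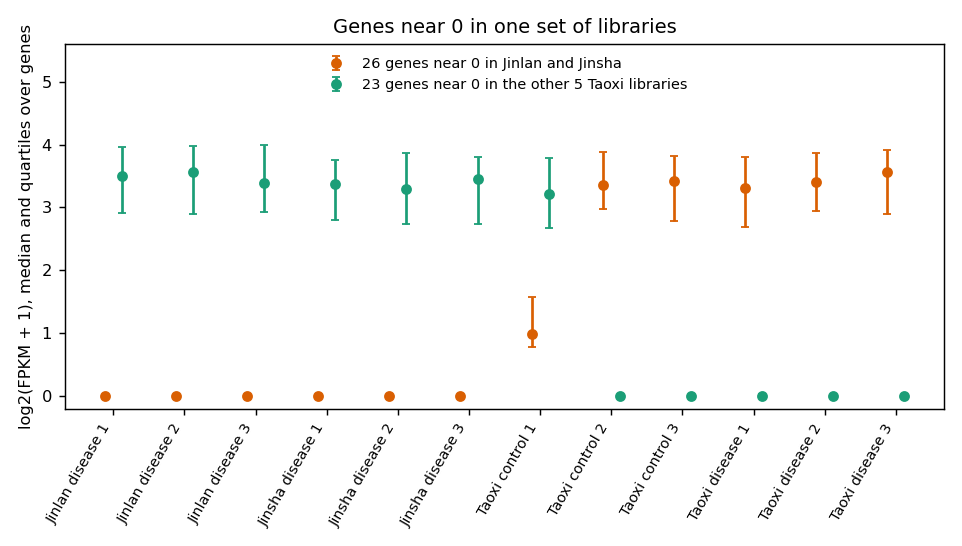
Levels of 2 sets of genes in each of the 12 libraries (x axis), as log2(FPKM + 1) on the y axis, with points for the median over the genes and bars for the quartiles. The 26 IDs of the first set have a median of 0.987 FPKM in Taoxi control 1, against 8.89 to 10.8 FPKM in the other 5 Taoxi libraries and 0 in Jinlan and Jinsha. The 23 IDs of the second set have a median of 8.26 FPKM in Taoxi control 1 and 0 in the other Taoxi libraries.

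Diseased and control fruit were first compared within Taoxi, the cultivar with both states. Of 17421 genes, 777 were higher and 597 lower in diseased fruit (limma, adjusted p below 0.05), and among these 194 were higher and 107 lower by at least 2-fold. The largest rises were those of NewGene_4547, from 0.114 ± 0.129 FPKM in control to 34.7 ± 22.0 FPKM in diseased fruit (SD, n = 3), and of Cg2g041640, from 9.75 ± 4.87 to 243 ± 116 FPKM (SD, n = 3). Their log2 fold changes were 4.84 ± 0.35 (SE, limma adjusted p = 0.000108) and 4.53 ± 0.40 (SE, limma adjusted p = 0.000323). In a fit of the 6 Taoxi libraries alone, Cg2g041640 had an adjusted p of 0.0545 (limma). In the diseased fruit of the other cultivars NewGene_4547 stood at 0.264 ± 0.236 FPKM in Jinlan and 3.19 ± 0.85 FPKM in Jinsha (SD, n = 3), and Cg2g041640 at 23.3 ± 3.8 and 9.87 ± 2.55 FPKM (SD, n = 3).

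The largest falls were those of Cg6g009720 and Cg2g033970. Cg6g009720 stood at 1830 and 1825 FPKM in Taoxi controls 2 and 3 and at 349 FPKM in Taoxi control 1, and fell to 161 ± 35.6 FPKM in diseased fruit (SD, n = 3). Its log2 fold change was -2.72 ± 0.52 (SE, limma adjusted p = 0.0129), and -3.52 ± 0.18 without Taoxi control 1 (limma adjusted p = 2.32e-06). Diseased Jinlan and Jinsha held this gene at 125 ± 10.6 and 182 ± 35.4 FPKM (SD, n = 3). Cg2g033970 was at 62.2 FPKM in Taoxi control 1 and at 13.5 and 12.5 FPKM in Taoxi controls 2 and 3, against 3.03 ± 1.26 FPKM in diseased fruit (SD, n = 3). Its log2 fold change was -2.58 ± 0.51 (SE, limma adjusted p = 0.0142) with all controls and -1.85 ± 0.25 (limma adjusted p = 0.000397) without Taoxi control 1. Diseased Jinlan and Jinsha held Cg2g033970 at 24.4 ± 4.4 and 64.7 ± 12.9 FPKM (SD, n = 3). Both falls missed the threshold in the fit of the Taoxi libraries alone (limma adjusted p = 0.177 for Cg6g009720 and 0.179 for Cg2g033970) and without diseased Taoxi 1 (limma adjusted p = 0.0516 and 0.0638).

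**Figure D3:**
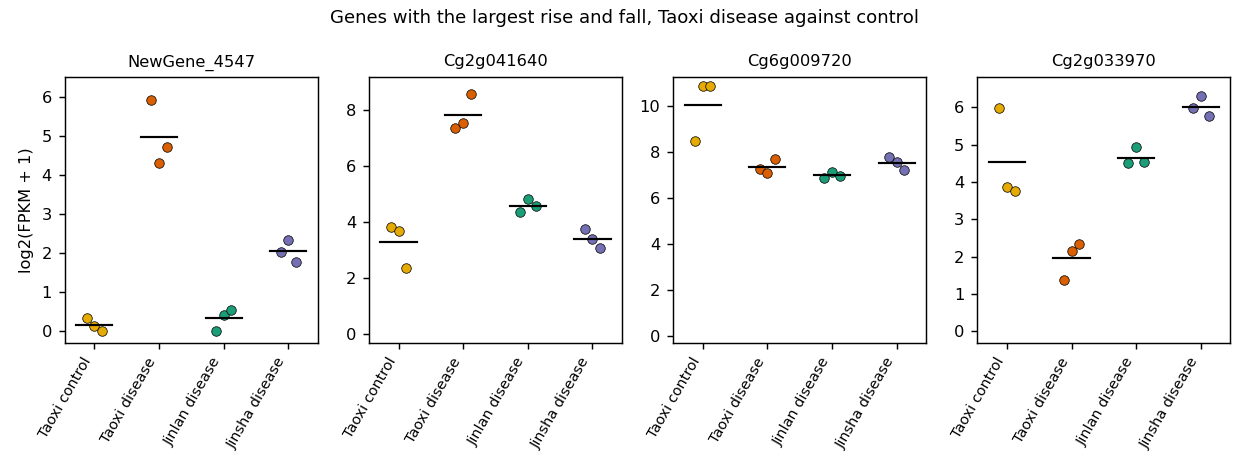
Levels of the 4 IDs with the largest rises and falls in diseased Taoxi fruit, as log2(FPKM + 1) on the y axis, with 1 point per library and a line at the mean of the 3 libraries of each group (x axis). NewGene_4547 and Cg2g041640 are higher in all 3 diseased Taoxi libraries than in any control, and the highest Taoxi control point of Cg2g033970 is Taoxi control 1, at 62.2 FPKM.

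The share of genes that passed was 6.37% of 7950 genes below a mean of 10 FPKM over the 12 libraries, 8.63% of 8343 genes from 10 to 100 FPKM, and 13.1% of 1128 genes at 100 FPKM or more. Without Taoxi control 1 the count rose to 3277 genes higher and 1929 lower, among which 571 and 204 by at least 2-fold. All 777 genes that were higher with all controls were higher without it, and 590 of the 597 lower genes were lower. Both fits share all the other libraries, and the spread is smaller without Taoxi control 1, so these counts are no independent check. Across genes, the log2 fold changes with and without Taoxi control 1 correlated at 0.788. Leaving out diseased Taoxi 1, 2 or 3 instead left 583, 696 or 672 passing genes, and a fit of the 6 Taoxi libraries alone left 11, of which 10 were higher. The fit over all 12 libraries gives each gene a single spread for all groups, while the Taoxi controls spread more widely than the others. Its standard errors and p-values for the Taoxi comparison with all controls may therefore be too small. The fit of the Taoxi libraries alone also rests on fewer libraries, and the share of each in the lower count was not tested.

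**Figure D4:**
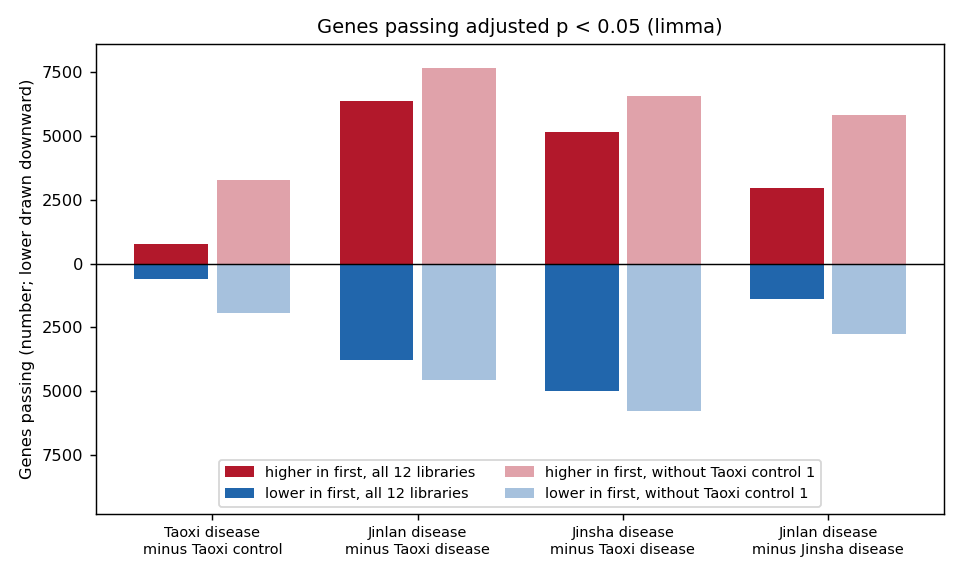
Number of genes passing at an adjusted p below 0.05 (limma) in the 4 comparisons on the x axis, with genes higher in the first-named group drawn upward and genes lower drawn downward, for all 12 libraries (full colour) and without Taoxi control 1 (pale). The Taoxi comparison goes from 1374 to 5206 passing genes and that of Jinlan with Jinsha from 4341 to 8592.

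Diseased fruit of the cultivars was compared next. Cultivar and response to disease are not separated in these comparisons, since they hold no control fruit of Jinlan or Jinsha. Against diseased Taoxi, diseased Jinlan had 6358 genes higher and 3788 lower, 58.2% of those tested, with 1894 higher and 1445 lower by at least 2-fold. NewGene_3937 was at 68.6 ± 3.8 FPKM in Jinlan (SD, n = 3) and at 0.0312, 0 and 0 FPKM in the 3 diseased Taoxi libraries (limma adjusted p = 0.00218). In Taoxi control 1 it stood at 42.3 FPKM. Cg4g015450 was at 138 ± 4.7 FPKM in Jinlan and 1.37 ± 0.42 FPKM in diseased Taoxi (SD, n = 3), a log2 fold change of 5.89 ± 1.39 (SE, limma adjusted p = 0.00569). In the opposite direction, Cg2g017880 was at 0.275 ± 0.170 FPKM in Jinlan against 144 ± 3.1 FPKM in diseased Taoxi, and Cg9g006330 at 2.44 ± 0.45 against 313 ± 33.6 FPKM (SD, n = 3). Their log2 fold changes were -6.84 ± 0.56 (SE, limma adjusted p = 0.000108) and -6.51 ± 0.56 (SE, limma adjusted p = 0.000131). The spread of these 4 IDs came largely with Taoxi control 1, a library outside this comparison. Without it the standard errors were 0.11 for NewGene_3937 (1.13 with it), 0.19 for Cg4g015450, 0.11 for Cg2g017880 and 0.13 for Cg9g006330. At 0 FPKM in all 3 Jinlan libraries and at 1 FPKM or more in all 3 of diseased Taoxi were 56 IDs, and 37 IDs showed the reverse.

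Diseased Jinsha differed from diseased Taoxi in about as many genes, with 5162 higher and 4975 lower (1944 and 1514 by at least 2-fold). NewGene_3937 was at 109 ± 19.7 FPKM in Jinsha (SD, n = 3, limma adjusted p = 0.000859). Cg2g044400 was at 340 ± 67.6 FPKM in Jinsha, 50.6 ± 4.9 FPKM in Jinlan and 3.17 ± 0.24 FPKM in diseased Taoxi (SD, n = 3), a log2 fold change of 6.33 ± 0.69 between Jinsha and Taoxi (SE, limma adjusted p = 0.000122). Cg7g006970 was at 0.620 ± 0.252 FPKM in Jinsha against 157 ± 24.0 FPKM in diseased Taoxi, and Cg3g004300 at 1.44 ± 0.56 against 192 ± 75.8 FPKM (SD, n = 3). Their log2 fold changes were -6.61 ± 0.55 (SE, limma adjusted p = 3.91e-05) and -6.26 ± 0.59 (SE, limma adjusted p = 6.06e-05). Without Taoxi control 1 the standard errors were 0.13 for Cg2g044400, 0.14 for Cg7g006970 and 0.25 for Cg3g004300. Both were also low in diseased Jinlan, at 2.21 ± 0.16 FPKM for Cg7g006970 and 4.93 ± 0.50 FPKM for Cg3g004300 (SD, n = 3). At 0 FPKM in all 3 Jinsha libraries and at 1 FPKM or more in diseased Taoxi were 59 IDs, and 34 showed the reverse.

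Jinlan and Jinsha often differed from diseased Taoxi in the same genes and direction. In both, 3954 genes were higher and 2990 lower, against 1884 and 1082 for independent lists of these sizes, and 225 genes passed in opposite directions. The log2 fold changes of the 2 comparisons correlated at 0.862 across genes, which are not independent replicates, where 20 simulations of unchanged groups that share the Taoxi libraries gave a mean of 0.499. The covariance was 0.753 against 0.0326 in the simulations, a difference of 0.720. The simulated unchanged groups shared 0.05 calls on average. Almost no gene passes where no group differs, so this count does not measure what the shared libraries add to the overlap. Part of the overlap may come from those libraries, which are too few to split. Without Taoxi control 1, diseased Jinlan differed from diseased Taoxi in 7657 higher and 4561 lower genes and diseased Jinsha in 6578 and 5793. In both, 5524 genes were then higher and 3775 lower, against 2901 and 1522 for independent lists, and 483 passed in opposite directions.

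Diseased Jinlan and Jinsha were nearer to each other than to Taoxi, with group means that correlated at 0.965 across genes against 0.883 and 0.877 with diseased Taoxi. In Jinlan 2950 genes were higher and 1391 lower than in Jinsha (limma, adjusted p below 0.05). Among differences of at least 2-fold the balance was the reverse, with 244 higher and 507 lower in Jinlan. Cg7g000360 was at 58.5 ± 0.61 FPKM in Jinlan against 6.63 ± 0.87 FPKM in Jinsha (SD, n = 3), a log2 fold change of 2.97 ± 0.11 (SE, limma adjusted p = 8.64e-07), and at 83.0 ± 7.9 FPKM in diseased Taoxi. Cg5g018510 was at 80.6 ± 5.6 against 12.7 ± 2.0 FPKM (SD, n = 3), a log2 fold change of 2.58 ± 0.28 (SE, limma adjusted p = 0.000265), with a standard error of 0.11 without Taoxi control 1. CgUng020190 was at 0.354 ± 0.081 FPKM in Jinlan and at 7.96, 48.0 and 74.3 FPKM in the 3 Jinsha libraries (limma adjusted p = 0.000594). Cg5g030110 was listed at 0 in all 3 Jinlan libraries and at 42.2, 26.7 and 7.75 FPKM in Jinsha (limma adjusted p = 0.00659). At 0 FPKM in all Jinlan libraries and at 1 FPKM or more in all Jinsha libraries were 2 IDs, and none showed the reverse.

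The balance of higher against lower genes varied with the scaling of the FPKM. Over all genes tested, the median log2 difference was 0.15 between diseased Jinlan and Taoxi and 0.11 between Jinlan and Jinsha. Median-ratio scaling moved these medians by -0.15 and -0.11, and quantile normalization moved the first by -0.11. With median-ratio scaling, which brings these medians near 0 by its construction, the share of passing genes that were higher in Jinlan went from 62.7% to 49.0% against Taoxi and from 68.0% to 45.0% against Jinsha. The other scalings kept a majority higher in Jinlan, at 60.2% (upper quartile), 54.8% (quantile) and 63.2% (TPM) against Taoxi and at 56.8%, 58.6% and 66.5% against Jinsha. Within Taoxi the share of passing genes that were higher in diseased fruit was 56.6%, and 47.0% with upper-quartile scaling and 47.8% with quantile normalization. Without Taoxi control 1, which enters the comparison of Jinlan with Jinsha through the shared spread and the filter on low values, 5815 genes were higher and 2777 lower. Leaving out any 1 of the 6 Jinlan and Jinsha libraries left 2512 to 2887 passing genes.

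The genes that differed with disease in Taoxi were then followed in Jinlan against Jinsha, a comparison with which the Taoxi one shares no library. The Taoxi comparison does hold Taoxi control 1, which lay nearer to diseased Jinlan than to the other Taoxi controls. Both comparisons may be tied through that library, so the values without it are given below. Of the 777 genes higher in diseased Taoxi, 153 were higher and 133 lower in Jinlan than in Jinsha. The share that was lower, 17.1%, exceeded the 7.56% of the other genes tested (Fisher's exact test, two-sided, adjusted p over 4 tests = 5.90e-17), and the share that was higher was 19.7% against 16.8% (Fisher's exact test, adjusted p = 0.0397). Of the 597 genes lower in diseased Taoxi, 170 (28.5%) were higher and 89 (14.9%) lower in Jinlan, against 16.5% and 7.74% of the other genes (Fisher's exact tests, adjusted p = 1.98e-12 and 1.09e-08). These tests treat genes as independent, which they are not, and both comparisons take each gene's spread from 1 fit, so genes with a small spread pass more readily in both. Among 10000 random sets of other genes matched on that spread and on mean expression, the median was 60 lower genes for the set higher in diseased Taoxi (133 observed), and 120 higher and 49 lower genes for the set lower in diseased Taoxi (170 and 89 observed). No random set reached these 3 counts (permutation test, two-sided, p = 0.0002 each, the smallest these sets can give, and adjusted p over 4 tests = 0.000267). The permutation tests, here and below, draw genes and not libraries at random, so they too treat genes as independent. The estimated correlation between genes was 0.051 in the set higher and 0.077 in the set lower in diseased Taoxi. These p-values may therefore be too small. The 153 higher genes of the set higher in diseased Taoxi did not exceed the matched sets, whose median was 169 (permutation test, adjusted p = 0.129). Neither set passed the test of moving one way relative to the other genes. Camera gave an adjusted p = 0.135 for the genes higher and an adjusted p = 0.880 for the genes lower in diseased Taoxi, and adjusted p = 0.835 and 0.955 with an estimated correlation. The set higher in diseased Taoxi had a median log2 difference of 0.05, a mean of -0.04 and a downward camera direction. With median-ratio scaling its median was -0.08, its camera adjusted p was 0.01665 (0.661 with an estimated correlation), and the share higher in Jinlan no longer passed (10.1% against 8.79%, Fisher's exact test, adjusted p = 0.197). The set lower in diseased Taoxi had a median of 0.11 and a mean of 0.07, with a downward camera direction.

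Without Taoxi control 1, 3277 genes were higher in diseased Taoxi, of which 32.0% were higher in Jinlan than in Jinsha against 33.8% of the other genes (Fisher's exact test, adjusted p = 0.0463) and 33.6% at the median of the matched sets (permutation test, two-sided, adjusted p = 0.0168). Of the same 3277 genes 20.3% were lower, against 15.0% of the other genes and 16.4% at the median of the matched sets (permutation test, two-sided, adjusted p = 0.0008). Of the 1929 genes lower in diseased Taoxi, 36.3% were higher and 19.7% lower in Jinlan, against 33.1% and 15.5% of the other genes and 32.5% and 17.5% at the medians of the matched sets (permutation tests, adjusted p = 0.0008 and 0.0064). Relative to the matched sets, these excesses were smaller than those with all controls, and came from longer lists of genes.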

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

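The overlap of Jinlan and Jinsha against Taoxi, library weights, and Taoxi control 1 left out of the comparisons it does not belong to, of the overlap and of the Taoxi genes in Jinlan against Jinsha, were chosen after the data had been seen. A fit of only the groups compared left 11 passing genes within Taoxi (10 higher, 1 lower) and gave 9257 for Jinlan against Jinsha (6186 and 3071), where the wide spread of Taoxi control 1 no longer entered. Library weights, which gave Taoxi control 1 a weight of 0.0401, gave 5525 passing genes within Taoxi (3514 and 2011) and 10082 for Jinlan against Jinsha (6745 and 3337). Leaving out 1 library gave 583 to 5206 within Taoxi (353 to 3277 higher, 230 to 1929 lower) and 2512 to 8592 for Jinlan against Jinsha (1637 to 5815 higher, 875 to 2777 lower), and in both the highest value is the one without Taoxi control 1. A fold threshold of 2 left 301 genes within Taoxi (194 and 107), 3339 for Jinlan against Taoxi (1894 and 1445), 3458 for Jinsha against Taoxi (1944 and 1514) and 751 for Jinlan against Jinsha (244 and 507), by its construction. Median-ratio scaling left 1541 genes higher in Jinlan than in Jinsha. The replicate number as a block left 889 passing genes within Taoxi, of which 356 lower. Of 18 pairs of libraries with the same number in different groups, 3 deviated from their group means with a correlation above 0.1 (range -0.21 to 0.17). Of the 12 libraries, 2 correlated best with their own number, so no pairing by number was seen. This check cannot exclude a pairing, since Taoxi control 1 sets most of the deviations among the Taoxi controls. For the Taoxi disease genes in Jinlan against Jinsha, the camera adjusted p of the genes higher in Taoxi became 0.01665 with median-ratio scaling and 0.001593 with the block, both downward, and both calls are lost with an estimated correlation (adjusted p = 0.661 and 0.297). The direction of the genes lower in Taoxi turned with the block, at an adjusted p of 0.8835. Over the settings run, the adjusted p of the first set ran from 0.001593 to 0.414 with the preset correlation and from 0.297 to 0.917 with an estimated one, and that of the other from 0.774 to 0.963 and from 0.917 to 0.984. The excess of genes higher both in diseased Taoxi and in Jinlan, 19.7% against 16.8%, was 14.1% against 14.0% with the block (Fisher's exact test, adjusted p = 0.949) and turned without Taoxi control 1 (32.0% against 33.8%, adjusted p = 0.0463). The cause was not tested where none is given. Genes that passed in opposite directions in Jinlan and Jinsha against Taoxi went from 225 to 483 without Taoxi control 1. The other counts of passing genes in the 4 comparisons, and of those passing the same way in both cultivars against Taoxi, stayed within 1.5 times. Of 300 refits of the named genes, 295 kept direction and threshold, 5 kept the direction at an adjusted p of 0.05 or more, and none turned. The 5 were Cg2g041640, Cg6g009720 and Cg2g033970 in the fit of only the groups compared, and Cg6g009720 and Cg2g033970 without diseased Taoxi 1. The gene list tests, with their alternatives, were not run, since the IDs carry no descriptions. Depth is unknown, so low values have no counting error.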

Other observations

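The tests on Taoxi control 1 (whole library, another genetic make-up or mix) and the first test on neighbouring IDs were chosen after the patterns had been seen, as were the tests of ID series.

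By the opening characters of their IDs, whose meaning the file does not state, the tested genes fall into 11 series. In Jinlan against Jinsha, genes of the series NewGene passed less often, at 20.7% of 1147 against 25.2% of the others (odds ratio 0.772, Fisher's exact test, two-sided, adjusted p over 44 tests = 0.0234), and so did those of the series CgUng, at 18.8% of 442 against 25.1% (odds ratio 0.691, adjusted p = 0.0475). The other 42 tests, over the 4 comparisons, had an adjusted p of 0.05 or more. At 100 FPKM or more and below 10 FPKM, the shares of genes that passed were 37.0% and 19.8% in Jinlan against Jinsha, 51.8% and 58.4% in Jinlan against Taoxi, and 61.4% and 55.5% in Jinsha against Taoxi. The difference between these shares was not tested. The tests of ID series were not matched on expression and treat genes as independent. They therefore cannot separate a lower share in the series NewGene or CgUng from a difference in expression level.

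Taoxi control 1 lay nearer to diseased Jinlan than to the other Taoxi controls. A library of diseased Jinlan or Jinsha fruit under a wrong label would hold the 26 Taoxi-only IDs below 0.02 of the level in Taoxi controls 2 and 3, but their median ratio was 0.125, the 10th percentile was 0.0887 and all 26 were above 0.02. A single Taoxi fruit of another genetic make-up, in which each of these genes is absent or present in 1 or 2 copies, would put most ratios below 0.02 or at 0.35 or more, but all 26 lay in between. A mix of Taoxi material with Jinlan- or Jinsha-like material may account for the pattern: the median ratios of 0.125 for Taoxi-only IDs and 0.812 for IDs absent from the other Taoxi libraries sum to 0.936 (0.887 in place of 0.812 when set against diseased Jinsha), and over 1243 genes at least 4-fold apart, 87.7% lay between Taoxi controls 2 and 3 and diseased Jinlan. Whether fruit, RNA or reads were mixed, and whether the source was Jinlan, Jinsha or material not analysed here, stays open (57 of 84 genes at least 4-fold apart between Jinlan and Jinsha lay nearer to Jinlan, in 1 library and with genes that are not independent), as does a genetic make-up that lowers these genes through their regulation, which was not tested.

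With Taoxi control 1 the Taoxi comparison had 1374 passing genes and without it 5206. A mix computed as 12.5% of the mean of Taoxi controls 2 and 3 and the rest of diseased Jinlan correlated with the real library at 0.987, against 0.977 for diseased Jinlan and 0.893 for Taoxi controls 2 and 3 alone. Put in the place of Taoxi control 1, it gave 866 passing genes, of which 796 were among the 1374 with the same direction. The range set beforehand for a mix as the cause, 916 to 2061, was missed on its lower side, so the mix as computed did not give the count of the real library and lowered it further. Its profile was assumed, from group means and 1 ratio, so a mix of another make-up stays open as a possible explanation of the drop.

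Among the Taoxi-only IDs and the IDs absent from the other Taoxi libraries, 37 carry a number within a series, and 2 pairs of them had consecutive numbers in the steps that the IDs use. The pairs were Cg5g042450 with Cg5g042460 and Cg2g016980 with Cg2g016990. Pairs further apart, such as Cg6g015640 with Cg6g015660, were not counted. Random sets matched on expression had a median of 0 pairs, and 8 of 10000 had as many. Neighbouring genes absent from, or different in sequence in, one cultivar against the reference may give such pairs. Among as many genes with the largest fold between the cultivar sets that are present in both, there were also 2 pairs, so neighbouring genes that change together whether or not they are absent give the same value, and with so few pairs both explanations stay open.

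The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many passing genes. The real count was 1374 within Taoxi, with 241 as the highest of the other splits, 10146 for Jinlan against Taoxi with 0, 10137 for Jinsha against Taoxi with 1, and 4341 for Jinlan against Jinsha with 1. The other splits put libraries of different groups together, so any difference between the groups widens the fitted spread. Low counts in those splits were therefore likely in advance, and they do not show how many genes would pass by chance.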
